A study of Helianthus annuus with 12 samples.

How the data were processed

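Small RNA libraries from leaves and roots of sunflower (Helianthus annuus) seedlings of the cultivar R5 were compared. Seedlings stood for 24 h in water holding 15% polyethylene glycol (PEG), a polymer that lowers the water potential around the roots, or in distilled water. There were 12 libraries in 4 groups of 3: control leaf, PEG leaf, control root and PEG root. The labels name Trizol for the RNA and BGI500 protocols for the libraries. They do not say whether leaf and root libraries with the same number came from the same plants, nor that replicates were separate plants, so every p-value measures only the spread between these libraries. Control leaf and control root libraries with the same number deviated together from their group means (correlations 0.225 to 0.262), a hint from the data and not from the labels, so the fit with the replicate number as a block is given beside the comparison of these groups where it differed.

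The authors deposited a table with raw counts of reads per small RNA feature and the same values in TPM, and the counts were used here. The deposited TPM values equalled the count scaled to the column total (CPM) in 100% of cells within a tolerance of 0.0051 and were not divided by length, with 0.001 written for a count of 0; they were used only for this check. The submitters' processing notes name Bowtie2 2.2.9 and Bowtie without a role. Mapping settings, the genome build and the releases of the microRNA and Rfam collections are not given in the sources used here. The file held 15903 entries, of which 3 counted all reads in exons, introns and between genes and name no feature. The other 15900 were 163 known microRNA names, 90 predicted microRNAs, 15055 siRNAs and Rfam families of other small RNAs. Predicted microRNAs and siRNAs had no count between 1 and 9, whereas the other classes did, so a 0 in these classes can stand for up to 9 reads.

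Total counts per library ranged from 20829490 to 33426228 and counts in named features from 3199001 to 6795847. Intervals of family changes are at a confidence level of 95% with 8 residual degrees of freedom. They and all lower bounds cover the spread of these libraries or counting error only, because reads carry no molecular identifiers. Against a group at 0 in every library, a fold was bounded with a floor of 9 counts per library for siRNAs and predicted microRNAs and 3 counts for other classes. These bounds use the TMM factors and change with other scalings.

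Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM factors and the quasi-likelihood test (glmQLFit, glmQLFTest) with a mean per group over all 12 libraries. Features with at least 10 counts in at least 3 libraries were tested, 10604 in all. P-values were adjusted by the Benjamini-Hochberg method and features were called at an adjusted p under 0.05 with no fold minimum. The comparisons were PEG versus control in leaves, PEG versus control in roots, the difference of these PEG effects, and roots versus leaves in control plants. Class shares of all reads were compared by two-sided exact permutation tests, whose smallest p with 3 against 3 libraries is 0.1.

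MicroRNA names in the file are borrowed from several species and near-identical names share a family, so counts were also summed per family over known and predicted microRNAs alone and tested the same way, with CPM relative to microRNA counts. This family test covered 124 families, 34 of them known, and was chosen after the data had been seen. Lists of families were fixed by their known targets: regulators of transcription factors, auxin signalling, copper and oxidative stress, phosphate and sulphate nutrition, the small RNA pathway, regulators of NLR disease resistance genes, families tied to drought and ABA, families conserved across seed plants, animal microRNA families as a check for foreign RNA, and rRNA, tRNA, snRNA and snoRNA as a check for degradation. Lists with at least 3 tested members, 9 of 10, were tested with camera (preset correlation 0.01, and an estimated correlation) and fry in limma 3.58.1, adjusted over the lists of a comparison. The lists overlap, and camera compares a list with all other features, most of which are siRNAs.

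Named features followed a rule fixed before the data were examined, as were the comparisons, tests, lists and most alternatives. Where features passed, the rule takes up to 10 with the largest increase and 10 with the largest decrease among those whose 2 groups did not overlap (for the difference of effects, among all that passed) and whose mean count was at least 10. Where fewer than 5 passed, it takes the 5 with the smallest p. It adds 2 to 4 members of each list with the smallest p, features past the threshold in both organs, and the 5 most abundant features of each group. The rule was also applied within microRNAs, a decision taken after the file's structure was seen and before fold changes were seen. Alternatives were other scalings, DESeq2 1.42.0, limma voom, other count minimums, a 2-fold minimum, replicate numbers as a block, the 6 libraries of the compared groups alone, family sums, and each library left out in turn. Added after the data were seen were zeros set to 9, all reads as library size, microRNAs alone, and siRNAs left out.

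The test was tried on simulated counts with the fitted dispersions of these data around a common mean per feature. Apart from the changes put in, groups did not differ, and counts under 10 were not written as 0. Changes of features were put only into the more abundant ones. The rates therefore need not hold for small counts against 0. In leaves the test recovered 0% of features changed 2-fold, 14% of those changed 4-fold, 40.8% at 8-fold and 70% at 16-fold, with 2 false calls among 7735 features. In roots it recovered 4% at 4-fold. For the difference of effects it recovered 0% at 4-fold, 6% at 8-fold and 18% at 16-fold. The family test recovered 24.2% of families changed 4-fold.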

Results

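Small RNA was sequenced from leaves and roots of R5, a sunflower cultivar described by the submitters as drought tolerant, after 24 h in 15% polyethylene glycol (PEG) or water, with 3 libraries per group. Total counts were 31583451 to 33154566 in control leaves, 30922418 to 33426228 in PEG leaves, 20829490 to 22433591 in control roots and 24163833 to 27248037 in PEG roots. Between 79.7% and 86.0% of counts fell in entries that name no small RNA. Known microRNAs made up 9.11% ± 0.227 of all reads in control leaves (SD, n = 3), 8.79% ± 1.13 in PEG leaves, 1.17% ± 0.652 in control roots and 2.05% ± 0.207 in PEG roots. Predicted microRNAs made up 2.60% ± 0.390 of reads in control leaves and 10.1% ± 1.58 in control roots. siRNAs made up 6.10% ± 0.323 and 2.10% ± 0.741. Each of these 3 classes differed between control roots and control leaves without overlap (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). Ribosomal RNA fragments held 2.27% ± 0.169 of reads in control roots and 1.20% ± 0.0574 in PEG roots, against 0.211% ± 0.0998 in control leaves and 0.335% ± 0.116 in PEG leaves.

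**Figure D1:**
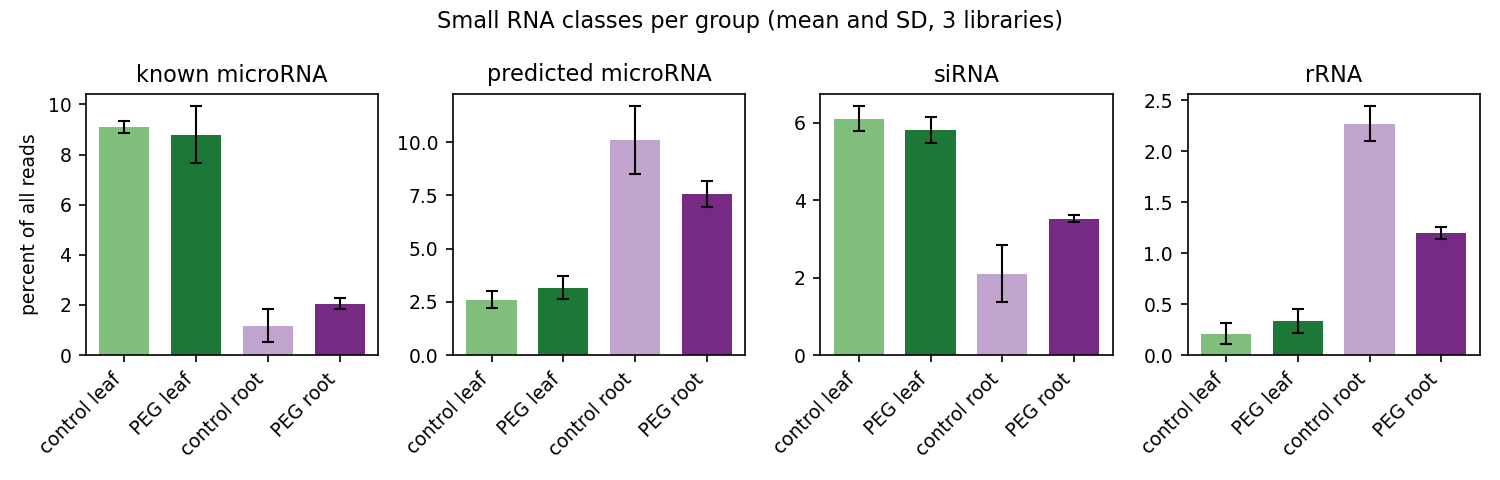
Mean percent of all reads in each group (bars) with the SD over 3 libraries (lines) for known microRNAs, predicted microRNAs, siRNAs and rRNA. Known microRNAs held 9.11% of reads in control leaves and 1.17% in control roots, predicted microRNAs 2.60% and 10.1%.

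Named-feature counts of leaves were dominated by known families. miR166, which targets HD-ZIP III transcription factors, held 16.8% ± 1.47 of named-feature counts in control leaves (n = 3), miR398, which targets copper/zinc superoxide dismutase transcripts, 12.5% ± 2.38, and miR167, which targets auxin response factors, 7.87% ± 2.10. In PEG leaves these shares were 13.4% ± 1.57, 12.4% ± 1.39 and 7.09% ± 0.497. Named-feature counts of roots were dominated by predicted microRNAs. In control roots novel_mir9 held 12.1% ± 6.62, novel_mir79 10.7% ± 3.56 and novel_mir20 9.96% ± 3.34, and in PEG roots 5.63% ± 1.04, 7.51% ± 4.40 and 7.19% ± 1.61. The most abundant single names in leaves were miR398b_2, miR166h-3p_1, miR167d_1, miR166a-3p and miR166u in controls, with miR167d-5p and miR396f_1 among the first 5 under PEG. In roots they were novel_mir9, novel_mir20, novel_mir79, novel_mir58 and the eukaryotic small subunit rRNA (RF01960) in controls, with novel_mir10 in place of novel_mir58 under PEG.

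The leaf comparison asks which small RNAs respond to drought-like stress above ground. Among known families only miR160, which targets auxin response factors, passed the threshold, and 5 of 34 had an unadjusted p under 0.05. Summed over its 7 names, miR160 rose from 232 ± 128 CPM in control leaves to 4483 ± 2157 CPM in PEG leaves (SD, n = 3 each; log2 fold change 4.27, SE 0.93, 95% interval 2.13 to 6.41, adjusted p = 0.0324, edgeR), and each PEG leaf library lay above each control leaf library. The predicted microRNA novel_mir21 rose from 792 ± 649 to 8567 ± 6637 CPM (log2 fold change 3.44, SE 0.68, adjusted p = 0.0300). novel_mir25 rose from 1.07 ± 1.86 to 38.0 ± 32.3 CPM (adjusted p = 0.0466). Its control leaf libraries held 0, 0 and 10 counts, so its control level is near the floor and not well measured. novel_mir12, at 0 in all 3 control leaves and in 1 PEG leaf library, reached 7.46 ± 6.75 CPM, at least 3.30-fold higher (adjusted p = 0.0466). These 4 of 124 families passed and all were higher, in a family test chosen after the data had been seen; 22 had an unadjusted p under 0.05, and DESeq2 called 15.

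**Figure D2:**
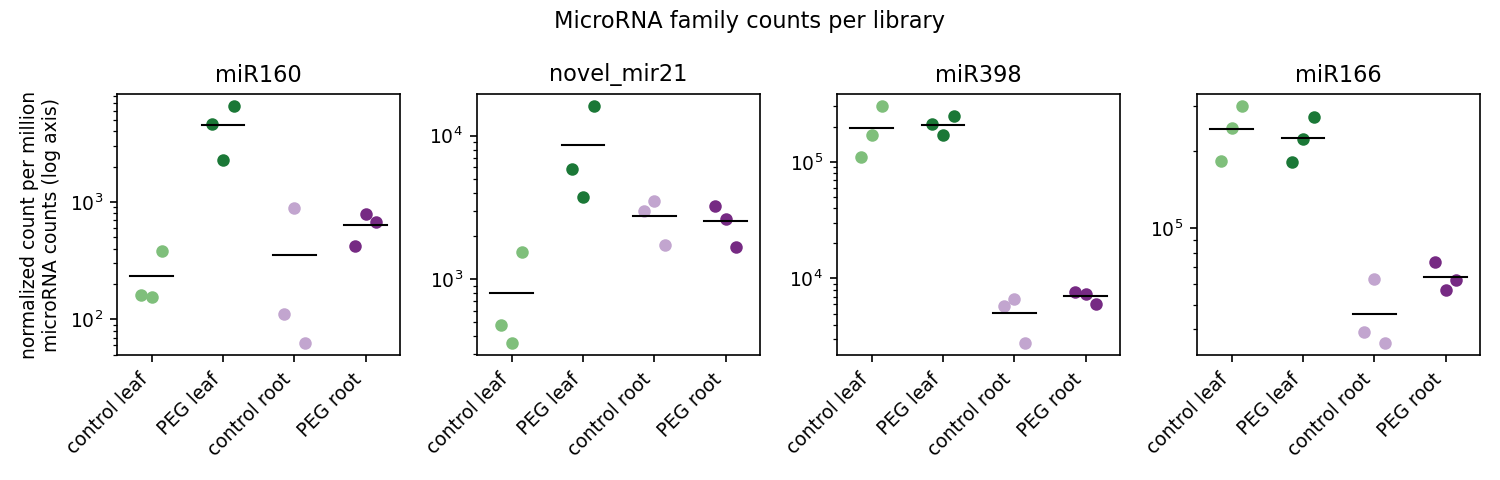
CPM relative to microRNA counts (log axis) of miR160, novel_mir21, miR398 and miR166 in each library (points) with the group mean (lines), for the 4 groups. miR160 averaged 4483 CPM in PEG leaves and 232 CPM in control leaves, while miR398 and miR166 lay lower in roots than in leaves.

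The most abundant leaf families did not pass. miR398 had a log2 fold change of 0.11 and miR166 of -0.11, both with overlapping libraries. miR396, which targets growth-regulating factors, had a log2 fold change of 0.93 (adjusted p = 0.274), miR394 2.44 (adjusted p = 0.183) and miR171, which targets GRAS transcription factors, -0.84 (adjusted p = 0.224). For miR396, miR394 and miR171 the PEG and control leaf libraries did not overlap, as for 26.0% of all tested microRNA names. Tested name by name as planned, 0 of 10604 features passed in edgeR, with 382 at an unadjusted p under 0.05, while DESeq2 called 30 and limma voom 181. The 5 smallest p-values belonged to novel_mir21 (log2 fold change 3.48, adjusted p = 0.703) and the siRNAs novel_sir4965, novel_sir2402, novel_sir14483 and novel_sir4579 (adjusted p = 0.703 each). Among microRNAs they belonged to novel_mir21, miR160_1 (log2 fold change 6.10), novel_mir25 (5.38), miR171e-5p (-1.59) and miR171f_3 (-1.24).

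Of the auxin signalling names, 0 of 19 were called over all features and 3 were higher when adjusted over the list alone: miR160_1, miR160b_1 (log2 fold change 2.46) and miR393a-5p (2.94), the last a regulator of auxin receptor transcripts. camera placed this list higher (adjusted p = 0.0015), but adjusted p = 0.195 with an estimated correlation. The copper list was placed higher (adjusted p = 0.0456; adjusted p = 0.195 with an estimated correlation; fry adjusted p = 0.0375), with miR398a-3p_1 (log2 fold change 3.76) the 1 name of 8 higher when adjusted over the list alone. The phosphate list (adjusted p = 0.0015) and the conserved families (adjusted p = 0.0200) were also placed higher, each with adjusted p = 0.195 with an estimated correlation. Regulators of transcription factors (adjusted p = 0.840), drought families (adjusted p = 0.160), the small RNA pathway (adjusted p = 0.0848) and animal families (adjusted p = 0.840) did not pass. The rRNA, tRNA, snRNA and snoRNA list was placed higher in PEG leaves (adjusted p = 3.7e-06; adjusted p = 0.339 with an estimated correlation), with 0 of 58 members called. No name of an NLR regulator family was in the file, so this list was not tested. The family calls rest on few libraries: none was left without control leaf replicate 1 or 2, and 25 families passed without control leaf replicate 3. Over 18 settings the log2 fold change of novel_mir21 ranged from 2.78 to 4.35, of novel_mir25 from 3.86 to 9.93 and of novel_mir12 from 1.76 to 8.15. Root-abundant families stood at a median of 1.32% to 2.42% of their control root level in PEG leaves and at 0.388%, 0.372% and 1.47% in control leaves.

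**Figure D3:**
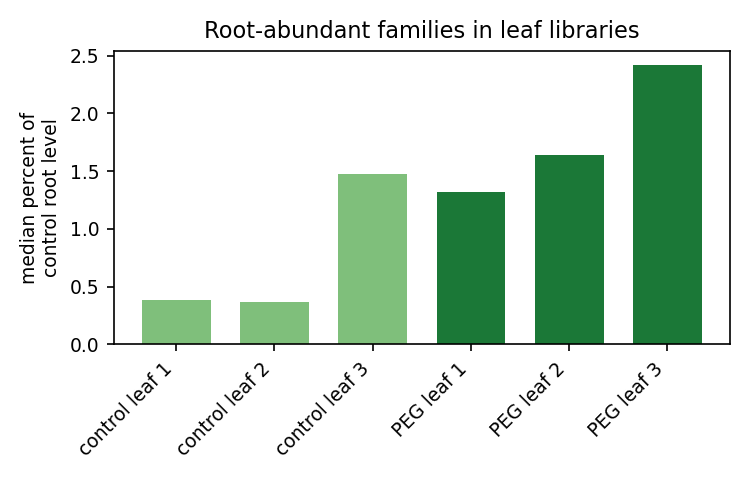
Median percent of the control root level (bars) over 31 families at least 16 times higher in root than in leaf libraries, in each leaf library. Control leaf libraries 1 and 2 stood at 0.388% and 0.372%, the other leaf libraries between 1.32% and 2.42%.

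In roots the comparison asks the same of the organ in direct contact with PEG. The fragments of ribosomal and small nucleolar RNA fell: the family of bacterial large subunit rRNA (RF02541), which plastid and mitochondrial rRNA also resemble, went from 56986 ± 16944 to 6604 ± 1524 TMM-scaled CPM of named-feature counts (log2 fold change -3.11, SE 0.37, adjusted p = 0.00487; -2.22 with library totals alone). The small nucleolar RNAs snoR86 (RF00303, log2 fold change -4.16, adjusted p = 0.0194; -2.44 without control root replicate 3), snoR126 (RF01426, -2.45, adjusted p = 0.0197) and snoR14 (RF01280, -1.95, adjusted p = 0.0479) fell with it. Of the 58 tested rRNA, tRNA, snRNA and snoRNA families, 4 fell over all features, 46 when adjusted over the list alone, and none rose. Of these 4 only RF02541 passed with every single library left out, snoR126 and snoR14 did not pass with library totals alone (adjusted p = 0.217 and 0.279), and none of the 4 passed with siRNAs left out or with zeros set to 9. The shares of all reads were lower in PEG roots, without overlap for rRNA and for snoRNA (exact permutation p = 0.1 each). Most other classes reached the same p without overlap. Known microRNAs went from 1.17% to 2.05% of all reads and siRNAs from 2.10% to 3.53%. Predicted microRNAs went from 10.1% to 7.57%, and snRNA and tRNA shares were lower too. The lower rRNA and snoRNA shares are thus part of a wider shift in composition. camera placed the list lower (adjusted p = 4.6e-56; adjusted p = 0.0301 with an estimated correlation; fry adjusted p = 0.0736). No microRNA family passed.

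Over all features 230 of 10604 passed in PEG roots, 223 higher and 7 lower, with 1247 at an unadjusted p under 0.05. Of these, 226 were siRNAs, 3 snoRNAs and 1 rRNA. Of the higher ones, 222 siRNAs had 0 in all 3 control roots and 10 to 142 counts (median 15) in PEG roots, so most of these calls rest on small counts. The 10 with the largest fitted increase, among them novel_sir10386, novel_sir16281 and novel_sir13737, were at least 1.34-fold to 4.37-fold higher. The siRNAs novel_sir14414 (log2 fold change -3.58) and novel_sir11275 (-1.74) fell, but their calls, like those of novel_sir10386 and novel_sir16281, ended with most single libraries left out. novel_sir16402, singled out after its values were seen, was the 1 siRNA above 0 in every root library that rose, from 13.8 ± 4.01 to 137 ± 22.0 CPM (log2 fold change 3.30, adjusted p = 0.0119). With each 0 of the siRNAs and predicted microRNAs set to 9, 0 features passed, and without control root replicate 1, 539 did.

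No microRNA passed in roots by name in edgeR (38 of 219 at an unadjusted p under 0.05; 11 by DESeq2 and 1 by limma voom), nor by family (19 of 124 at an unadjusted p under 0.05; 22 by DESeq2). The smallest p by family belonged to novel_mir46 (6097 ± 4596 CPM in control roots, 1248 ± 354 in PEG roots, log2 fold change -2.29), novel_mir82 (1.33), novel_mir30, novel_mir27 (3.10) and novel_mir80 (1.38), with adjusted p = 0.262 each. By name they were novel_mir46 (-2.74, adjusted p = 0.0945), miR6300 (-2.63), miR171a_2 (-1.17), novel_mir44 (-1.33) and novel_mir82 (1.06). miR399, which targets a regulator of phosphate uptake, had a log2 fold change of 1.21 (adjusted p = 0.274). The auxin names miR160 (6.71) and miR160a-5p (-4.81) had opposite signs, and their family sum stood at 353 ± 462 CPM in control roots and 632 ± 191 in PEG roots. Drought families (81 names, 0 called) and regulators of transcription factors (70 names, 0 called) were placed lower by camera (adjusted p = 0.00757 each; adjusted p = 0.0301 each with an estimated correlation), although their medians were -0.03 and -0.02 and their means 0.12 and 0.00. Conserved families were placed lower (adjusted p = 0.0448; adjusted p = 0.137 with an estimated correlation) with a median of 0.02 and a mean of 0.18. Animal families (3 tested, adjusted p = 0.00273; adjusted p = 0.12 with an estimated correlation) were also placed lower, with mir-9 (-1.77) the 1 lower when adjusted over the list alone. With library totals alone, 1 of the 5 called lists kept its call. The drought, transcription factor and conserved lists then turned higher in camera without a call. With that scaling fry called them higher (adjusted p = 0.0214, 0.0293 and 0.0212), so their direction depends on scaling.

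The difference of the PEG effects asks whether roots and leaves responded differently. The bacterial large subunit rRNA family fell in PEG roots relative to its change in leaves (difference of log2 fold changes -4.25, SE 0.51, adjusted p = 0.0167), as did snoR126 (-3.50, adjusted p = 0.0221), snoR86 (-5.11, adjusted p = 0.0444) and the siRNA novel_sir7931 (-4.48, adjusted p = 0.0422). The snoRNA R12 (RF00204, -6.05, adjusted p = 0.0385) passed too, at 0 in some libraries. RF02541 passed with every single library left out (-3.25 with library totals alone), whereas snoR126, snoR86 and novel_sir7931 did not. Without control root replicate 3, snoR86 stood at -3.37 and novel_sir7931 at -3.49. With the replicate number as a block, 0 features passed, so the call of RF02541 ended there too. The rRNA, tRNA, snRNA and snoRNA list differed (camera adjusted p = 2.4e-47; adjusted p = 0.0224 with an estimated correlation; fry adjusted p = 0.104), with 4 of 58 lower, 35 when adjusted over the list alone.

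For microRNA families the difference was not called: 0 of 124 passed in edgeR, with 30 at an unadjusted p under 0.05 and 30 called by DESeq2. miR160 had a difference of -3.43 (adjusted p = 0.119), novel_mir21 -3.55 (adjusted p = 0.0737) and novel_mir46 -3.46 (adjusted p = 0.0737), and novel_mir21 and novel_mir46 passed in 8 and 7 of 18 settings. By name the smallest p belonged to novel_mir21 (-3.89, adjusted p = 0.0562), novel_mir46, novel_mir83, novel_mir10 and novel_mir2. Over all features 215 passed, 210 higher and 5 lower (1077 at an unadjusted p under 0.05). All 210 were siRNAs, such as novel_sir14351, novel_sir11262 and novel_sir13737, at 0 in all 3 control roots for those named. camera placed the auxin (adjusted p = 3.5e-05), conserved (adjusted p = 3.5e-05), drought (adjusted p = 0.000139), transcription factor (adjusted p = 0.0078), copper (adjusted p = 0.0157) and animal (adjusted p = 0.00423) lists lower. With an estimated correlation the adjusted p = 0.0414, 0.0224, 0.0223, 0.0224, 0.0479 and 0.10 in that order. None of these 6 passed with library totals alone. With zeros set to 9 or siRNAs left out, 0 features passed.

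Roots and leaves of control plants differed far more than PEG and control did. Of 34 known families, 25 passed, 19 lower and 6 higher in roots. miR398 stood at 193679 ± 98904 CPM in control leaves and 5104 ± 2049 in control roots (log2 fold change -5.25, SE 0.53, adjusted p = 4.75e-06), miR167 at 110523 ± 17083 and 7844 ± 1740 (-3.82), miR166 at 244215 ± 59003 and 45855 ± 15140 (-2.41) and miR168, which targets ARGONAUTE1 transcripts, at 50884 ± 21421 and 9109 ± 3323 (-2.48). miR393 (-5.28), miR170 (-9.89), miR397 (-2.89), miR162 (-2.54), miR858 (-2.53), miR171 (-1.92) and miR156 (-1.89) were lower as well. miR319, which targets TCP transcription factors, was higher, at 111 ± 48.9 CPM in leaves and 845 ± 560 in roots (2.93, adjusted p = 0.00123). miR390 (1.46), miR172 (1.60), miR477 (5.41), miR3630 (5.50) and miR6300 (6.81) were higher too. miR477 held 1, 3 and 0 counts in control leaves and 17, 91 and 3 in control roots. miR170 held 3, 5 and 1 counts in control roots. The size of the change is therefore not well measured for miR477 and miR170.

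**Figure D4:**
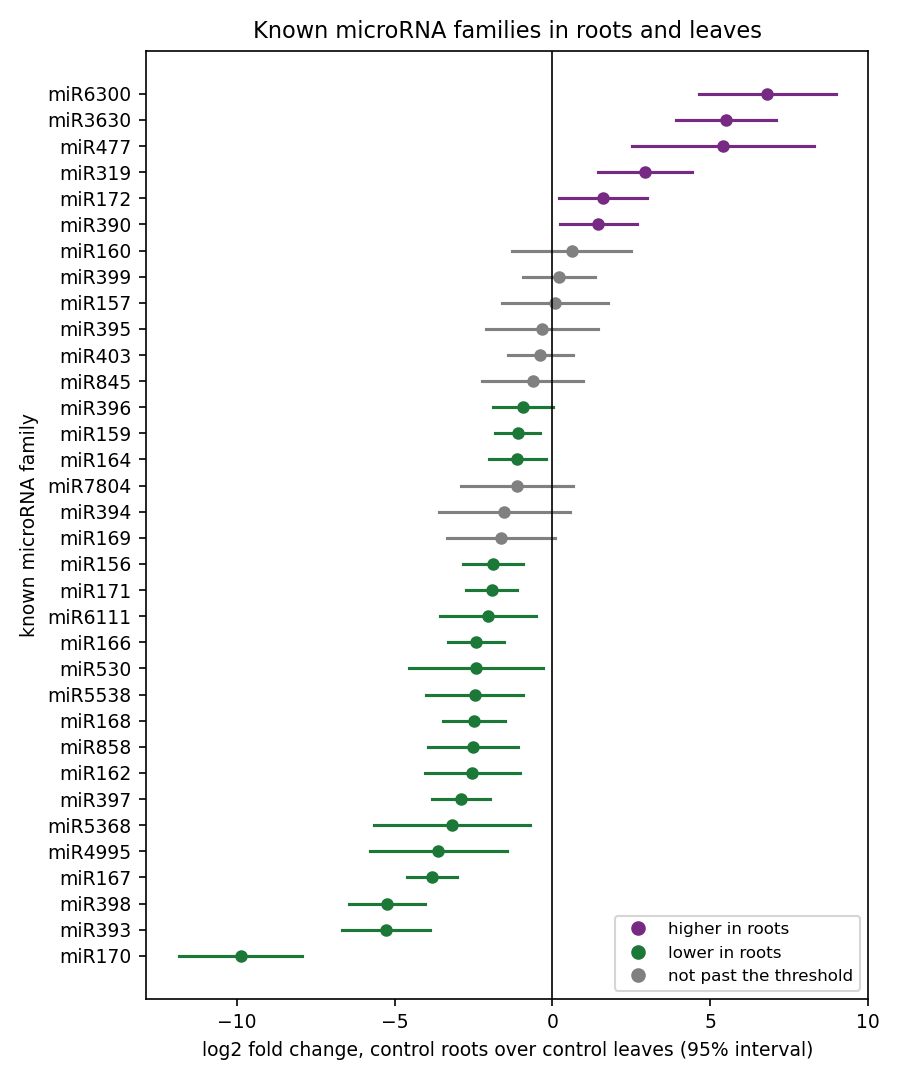
Log2 fold change of each known microRNA family in control roots over control leaves (points) with its 95% interval (lines). Of the 34 families, 19 were lower in roots, 6 were higher and 9 did not pass the threshold.

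By list, 9 of 11 families that regulate transcription factors passed, miR172 and miR319 higher and miR156, miR159, miR164, miR166, miR170, miR171 and miR396 lower. miR396 (-0.94, adjusted p = 0.0497) passed in 8 of 18 settings, miR164 and miR172 in 15 and miR390 in 14. With a library left out, miR858 moved to -1.62, miR477 to 4.02 and miR6300 to 5.86. Of the auxin families miR390 was higher and miR167 and miR393 lower, while miR160 did not pass (0.61, adjusted p = 0.495). Both copper families, miR397 and miR398, and miR162 and miR168 of the small RNA pathway were lower. Neither miR395 nor miR399 passed. None of the 25 known families that passed changed sign over 18 settings. Tested by name, the lists were placed by camera relative to other features, whose median was -4.75. The transcription factor (adjusted p = 0.00225), conserved (adjusted p = 0.00225), drought (adjusted p = 0.0423) and auxin (adjusted p = 0.0465) lists were thus placed higher although their medians were -0.35, -0.49, -0.82 and -1.32. In that order, fry gave them as lower with adjusted p = 0.0119, 0.00916, 0.000397 and 0.303, the auxin list without a call. With an estimated correlation their camera adjusted p = 0.0130, 0.0503, 0.0713 and 0.276. The copper list was placed lower (adjusted p = 0.0463; adjusted p = 0.0928 with an estimated correlation; fry adjusted p = 2.8e-05; camera adjusted p = 0.155 with the replicate block), the phosphate list higher (adjusted p = 0.00225; adjusted p = 0.136 with an estimated correlation) and the small RNA pathway was not called (adjusted p = 0.705; fry adjusted p = 0.0048, lower).

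Predicted microRNAs also differed between the organs. Of 90, 74 passed, 45 higher and 29 lower in roots. novel_mir10 stood at 861 ± 681 CPM in control leaves and 104279 ± 15402 in control roots (log2 fold change 6.92), novel_mir79 at 2080 ± 1646 and 192110 ± 44519 (6.53), and novel_mir69 was higher by 7.59. novel_mir43 (-5.19) and novel_mir29 (-5.22) were lower. By name, novel_mir12, novel_mir2 and novel_mir39 were at 0 in all 3 control leaves. With TMM scaling they were at least 446-fold, 368-fold and 316-fold higher in control roots. These bounds carry the TMM factor of 0.292 of control root replicate 3 and are lower with library totals. With library totals alone their fitted log2 fold changes of 14.41, 14.13 and 13.91 became 13.53, 12.93 and 12.87. novel_mir8 was at 0 in all 3 control roots and at least 25.4-fold lower. miR171b_2 (-7.66; -8.68 with library totals alone) was lower and its relative miR171a_1 (6.30) higher in roots.

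All 10 rRNA families, 41 of 43 snoRNAs, all 4 snRNAs and the tRNA were higher in control roots, 56 of these 58 together (camera adjusted p = 5.3e-85; adjusted p = 0.0130 with an estimated correlation). Over all features 2521 of 10604 passed, 581 higher and 1940 lower (4316 at an unadjusted p under 0.05), and 1158 with the replicate block. Of the 1894 siRNAs that were lower, 1701 had 0 in all 3 control roots, which had fewer counts than leaves; novel_sir10392, novel_sir4168 and novel_sir15930 were at least 68.3-fold, 57.7-fold and 41.0-fold lower. The balance depends on scaling: 23.0% of the called features were higher in roots, 12.8% with library totals alone and 10.7% of the 3886 called with all reads as library size. The animal families (2 of 3 higher, adjusted p = 0.00129; adjusted p = 0.0828 with an estimated correlation) were placed higher. Control root replicate 3 held 2131 counts of mir-451 against at most 1261 in any other library, and its TMM factor was 0.292 against 0.774 to 1.41 in the other libraries.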

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

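The tests of root RNA, of foreign RNA, of the count floor and of siRNAs as a class, and the bounds for the splits, were chosen after the results were seen; the test of the difference between organs was planned. That test called 215 features whose PEG effect differed between roots and leaves. Those above 0 in every library were RF02541 (bacterial large subunit rRNA, -4.25), RF01426 (snoR126, -3.50), novel_sir7931 (-4.48) and RF00303 (snoR86, -5.11), on the log2 scale. Among 100 splits of the libraries, the real one included, 6 gave as many features, the highest other 231, so chance is not excluded for the 215. For families, all 100 splits gave at least the 0 found, the highest other 2.

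With 10 splits of 6 libraries each, the real one included, the splits are too few for a share under 0.05 in the other comparisons. In leaves the real count was 0, reached by all 10 splits, with 0 the highest other. In roots it was 230, reached by the real split alone, against 104 as the highest other. For roots versus leaves it was 2521, reached by the real split alone, against 2 as the highest other. By family the counts were 4 (the real split alone, highest other 0) in leaves and 0 (10 splits, highest other 0) in roots. The family count for roots versus leaves was 99 (the real split alone, highest other 0).

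The 4 families higher in PEG leaves included some with more counts in roots than in leaves, and root RNA in the PEG leaf libraries is a candidate explanation that was weighed for each. For miR160 and novel_mir21 the excess in PEG leaves would need at least 285% of the control root level in CPM relative to microRNA counts. On that scale every PEG leaf library exceeded every root library, which argues against root RNA. In TMM-scaled CPM of named-feature counts, novel_mir21 stood at 4288 ± 3423 in PEG leaves and 2569 ± 681 in control roots. For novel_mir21 the argument therefore depends on the scale. novel_mir25 would need 16.4%, against at most 3.97% for 21 root-abundant families seen in leaves. These 21 were chosen as at least 16 times higher in root than in leaf libraries, which itself keeps their share low. novel_mir25 was not that much higher in roots, so the contrast cannot decide on root RNA for it. Its 16.4% rests largely on PEG leaf replicate 3, at 75.0 CPM against 15.0 and 24.0 in PEG leaf replicates 1 and 2. novel_mir12 would need 1.36%, within the range of the 21 families, so root RNA may account for it. A response to PEG, which the design names, stays open for miR160, novel_mir21 and novel_mir25, as a hypothesis on 3 libraries per group.

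Most siRNAs called higher in PEG roots were at 0 in control roots, and a candidate explanation is that counts under 10 were deposited as 0. None of the 79632 siRNA values above 0 was under 10, and with each 0 set to 9, 0 calls were left. The median fitted log2 change of these features went from 7.34 (median SE 0.95) to 0.52 (median SE 0.37), because the contrast of small counts with 0 was removed. At a median of 15 counts in PEG roots, such calls could hardly outlast zeros set to 9, whatever their true level. The setting also ended calls of features without a 0, such as RF02541. It therefore cannot decide whether the floor made these calls. A rise of siRNA reads as a class in PEG roots cannot be told apart from the spread between 3 libraries per group. The 760 siRNAs with a mean of at least 100 root counts shifted by 0.88 (log2 of their share). The SD among control roots was 0.68, with control root replicate 3 at -0.83 and replicates 1 and 2 at 0.29 and 0.40. Without control root replicate 3 the shift was 0.49, to which that SD does not apply. The lowest PEG root library stood at 0.78 and the highest control root library at 0.40. With 3 other selections of abundant siRNAs the shift was 0.64 to 0.67 against SDs of 0.53 to 0.54, each PEG root library above each control root library in all 4, and PEG, which the design names, stays open as untested.

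Control root replicate 3 stood apart in animal microRNA precursor families, such as mir-10 (45653 counts, at most 1306 elsewhere) and mir-193 (26099, at most 4 elsewhere). Of 10 families of the animal list found in the file, 9 had their highest share of reads there. Among these, mir-451 (2131 counts, 29 to 1261 elsewhere) and mir-9 (340 counts, 108 to 186 elsewhere) were seen in every library. mir-1, mir-122, mir-143 and mir-192 held only 2 to 9 counts in control root replicate 3, so the count of families is weak evidence. RNA of another organism in this library would give such a pattern. The ratio of mir-193 to mir-10 was 0.572 there and at most 0.00326 in the other 11 libraries, which argues against more of a source shared by all libraries. No biological explanation was tested, since no group differs in this way. Without this library, 222 features passed in roots, 222 in the difference of effects and 2298 in roots versus leaves.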

How the results depend on the processing

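Alternatives with zeros set to 9, all reads as library size or siRNAs left out, and every alternative of the family test, were chosen after seeing the data; the others were planned. Upper-quartile factors could not be fitted, because the 75% quantile of a library was 0. The cause of a change below was not tested unless stated.

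In leaves the count of 0 became 30 with DESeq2, 181 with limma voom, 37 with zeros set to 9, and 0 to 1 with a library left out (1 without control root replicate 3). Leaf and root of the same number as a block by plant (correlation 0.0021) were fitted with limma voom. That fit also gave 181, so the change came with limma voom and not with the block. In roots the 230 became 424 with DESeq2, 4 with a minimum of 100 counts (fewer features tested), 0 with zeros set to 9 and 0 with siRNAs left out. Leaving out a library gave 222 to 539: 539 without control root replicate 1, 431 without control root replicate 2 and 389 without PEG root replicate 1. The 215 of the difference of effects became 1 with no count minimum, 2 with a minimum of 100 counts, 0 with the replicate block, 0 with zeros set to 9, 0 with siRNAs left out, and 189 to 504 with a library left out: 504 without control root replicate 1, 381 without control root replicate 2 and 373 without PEG root replicate 1. The 2521 for roots versus leaves became 729 with a minimum of 100 counts, 1158 with the replicate block, 3886 with all reads as library size, 262 with siRNAs left out, and 2252 to 2786 with a library left out.

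By family, the 4 in leaves became 15 with DESeq2 and 2 with the replicate block. Leaving out a library gave 0 to 25: 0 without control leaf replicate 1 or 2, 25 without control leaf replicate 3, 7 without PEG leaf replicate 1, 1 without PEG leaf replicate 3 or PEG root replicate 2 or 3, and 2 without any control root replicate or PEG root replicate 1. miR160 passed in 13 of 18 settings (adjusted p 7.8e-06 to 0.191), novel_mir21 in 16, novel_mir25 in 7 and novel_mir12 in 5, all keeping their direction. In roots the 0 became 22 with DESeq2 and 0 to 1 with a library left out (1 without control root replicate 2). The 0 of the difference of effects became 30 with DESeq2, 13 with DESeq2 size factors, 11 with the replicate block, 8 with zeros set to 9, and 0 to 27 with a library left out: 27 without control leaf replicate 3, 17 without control root replicate 2, 12 without PEG leaf replicate 1 and 1 without PEG leaf replicate 2. The 99 for roots versus leaves stayed between 91 and 100. The number of list calls, 25, became 11 with an estimated correlation, 9 with library totals and 8 with fry, not all of them among the 25.

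Library totals moved the median log2 fold change of all features by -0.12 in leaves, 0.03 in roots, 0.23 in the difference and -0.31 between organs, and that of microRNAs by 0.78 in roots and -1.05 between organs. Libraries with the same number correlated at 0.225 to 0.262 between control leaves and control roots but at -0.222 to -0.166 between PEG leaves and PEG roots, and microRNA families at 0.196 to 0.294 between control and PEG roots but at -0.471 to -0.308 between PEG leaves and PEG roots. The numbers therefore hint at pairs in some groups and not in others, and the fits without the block were kept; each control root library correlated best with the control leaf library of its own number. The block left 96 families for roots versus leaves and 0 in roots. Counts under 10 of siRNAs and predicted microRNAs are not seen, and control roots had the fewest reads.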

Other observations

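The pair tests below were chosen after the result was seen. Several predicted microRNAs were seen in a single organ. novel_mir14, novel_mir16, novel_mir31, novel_mir32, novel_mir36, novel_mir53, novel_mir54, novel_mir70 and novel_mir81 were at 0 in all 6 leaf libraries, and in control roots novel_mir14 stood at 270 ± 257 CPM of named-feature counts (n = 3), novel_mir16 at 206 ± 169, novel_mir36 at 103 ± 27.3 and novel_mir53 at 82.3 ± 7.04. Against the floor of 9 counts per library, and with TMM scaling, these were at least 234-fold, 178-fold, 89.2-fold and 71.2-fold higher than in control leaves. With library totals these bounds are lower. Without control root replicate 3 the fitted log2 fold change of novel_mir14 went from 13.47 to 12.40 and that of novel_mir16 from 13.08 to 12.30, and with library totals alone to 12.16 and 11.87. novel_mir14 (90069376 to 90069565) and novel_mir16 (90109856 to 90110045) lie on the minus strand of the same deposited sequence, and novel_mir53 (44491743 to 44491875) and novel_mir54 (44495550 to 44495710) on the plus strand of another; the build is not given in the sources used here. novel_mir72 was at 0 in all 6 root libraries and at 17.9 ± 4.75 CPM in control leaves, at least 3.73-fold higher.

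Names within a family did not always move together. Over 18 families with 2 abundant names, the median within-group correlation of these names was 0.646, against 0.452 for names of different families. In the 4 families where both names varied with an SD of at least 1 on the log2 scale it was -0.674, negative in miR160, miR162 and miR167 and 0.984 in miR157. For miR167 the SD of the log2 share within groups was 2.66 and 2.54 for the names and 0.22 for their sum.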
